A study of Mus musculus with 2 samples.

How the data were processed

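Single-nucleus RNA sequencing libraries were made from mouse prefrontal cortex, the frontal part of the neocortex. Per the labels' protocols, tissue of 8-week-old mice was frozen, the tissue of 3 mice per group was pooled, and nuclei were released, stained with a DNA dye and sorted before droplet capture with a 3' kit. One library came from littermate controls carrying a Cre recombinase driven by the Vgat gene (Slc32a1), and the other from mice carrying that Cre together with a conditional heterozygous change of Mef2c. With 1 library per group, no spread between animals can be estimated, and no test between the groups was made.

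Per the submitters' processing notes, Cell Ranger 6.1.2, Seurat 4.1.0 and the genome build mm10 were used. Those notes, as available here, give no role or order for them. The gene annotation release, the handling of intronic reads, the thresholds on nuclei and the treatment of doublets are not given in the sources used here. The authors deposited, among the files used here, a list of barcodes and a list of features for each library. Both are text with no measured unit. A barcode is the 16-base tag that a droplet's bead gives to the RNA captured in it. A feature is a gene, or an added sequence, to which reads could be assigned. Read counts per gene and nucleus were not analysed here, so the depth per library is unknown, and no expression level, cell type or share of nuclei is reported. The planned sums of counts by cell class were therefore not made.

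Libraries were grouped by their sample titles. Each barcode list was checked for length, alphabet, suffix and repeated lines, and the lists were intersected on all 16 bases. Barcodes were divided into their first 7 and last 9 bases, a split chosen after seeing that both libraries held the same number of variants of each part. The product of those numbers was taken as the number of possible pairings, on the assumption that every pairing can occur. Shares of barcodes have exact Clopper-Pearson 95% intervals, which cover counting error only and say nothing of differences between animals. The overlap of independent, equally likely draws was the product of the list sizes divided by the number of possible pairings. A second prediction gave each part of the barcode its own frequency in each library. In that model the chance that a pairing was listed was 1 minus the exponential of minus the product of a first-part and a last-part rate, fitted to the totals of each part. The same rates gave the expected number of jointly listed barcodes that differ only at positions 8 and 9, within and across libraries. That comparison was tested on 4 simulated lists for each share of barcodes placed with a partner. The overlap procedure was tested on simulated data. In 3 simulated data sets of independent lists the ratio of overlap to prediction ran from 0.9999 to 1.0009, and in 3 data sets in which 20% of the control list had been copied into the other list it ran from 1.145 to 1.146.

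Feature identifiers were matched to GENCODE M21 on GRCm38, the assembly also called mm10. Coordinates are 1-based, and those of a gene with another identifier version are named as such. Exons of all transcripts of a gene were merged, and the rest of the gene's span was taken as intron. Overlap with another annotated gene was counted by span, separately by strand.

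Before the data were examined, 7 gene lists and 12 lists of cell type markers were fixed, together with the rule for naming genes. The rule named Mef2c and Slc32a1, up to 4 members of each list in list order, and every member not found. Some members that the rule would name are not reported here by name, and the counts and medians of their lists include them. Alternatives fixed at the same time left out the barcode suffix, matched 8 bases, used odd-numbered lines, used barcodes in 1 list only, counted features by symbol and matched symbols without regard to case. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.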

Results

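The series addressed how reduced function of MEF2C, a transcription factor, in GABAergic (inhibitory) cells affects the mouse prefrontal cortex. Its single-nucleus part comprised 2 libraries, 1 labelled CONTROL_F and 1 labelled cHET_F, each made from the pooled tissue of 3 mice. The lists examined hold the barcodes and the genes of each library and no read counts. The comparison that the design implies, gene expression in Mef2c conditional heterozygous against control nuclei, was therefore not analysed here. What follows describes which genes each library was counted against and which barcodes it listed.

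Both libraries were counted against the same features, so any gene with a row in one had a row in the other. The feature lists held 55404 rows each and differed in 0 rows. They comprised 55401 mouse genes with Ensembl identifiers and 3 added reporter sequences named Tdtomato, Egfp and Gfp, which encode fluorescent proteins. No feature carried the symbol Cre (0 of 55404 rows), so the driver recombinase had no row of its own under that name. Without regard to identifier version, 55141 mouse genes (99.5%) were found in GENCODE M21, of which 21897 were protein coding, 9911 were long noncoding RNA genes and 13517 were pseudogenes. The remaining 260 mouse genes were not matched. A symbol stood on more than 1 row in 107 cases, covering 217 rows, and such symbols do not identify a gene without the identifier.

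Mef2c, the gene whose dosage the design changed, had 1 row (ENSMUSG00000005583.16). The same identifier version lies in GRCm38 on chromosome 13 from 83504034 to 83667080, on the + strand. The gene is protein coding and spans 163 kb, longer than 94.0% of the protein-coding features matched. Its 31 annotated transcripts merge into 21 exonic segments of 15715 bp together, and 90.4% of the span is intron. No other annotated gene overlaps it on either strand. The other members of the MEF2 family were also present as 1 row each. Mef2a lies on chromosome 7 and spans 142 kb, Mef2b on chromosome 8 spans 27.8 kb, and Mef2d on chromosome 3 spans 29.7 kb. Mef2a and Mef2b overlap other genes on their own strand, and Mef2a and Mef2d overlap genes on the opposite strand.

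**Figure D1:**
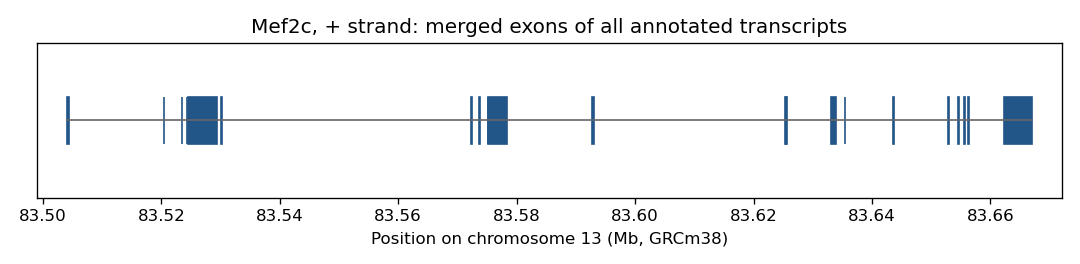
Map of Mef2c on chromosome 13 (x axis, position in Mb, GRCm38), with blue boxes for the 21 merged exonic segments and a grey line for the introns. The exons take up a small part of the 163 kb span, 90.4% of which is intron.

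Slc32a1, the vesicular GABA transporter gene whose Cre driver was used, had 1 row (ENSMUSG00000037771.11). It lies on chromosome 2 from 158610767 to 158615748, on the + strand, and spans 4.98 kb with 2 exonic segments. Introns make up 43.9% of its span, against 90.4% for Mef2c and a median of 79.6% over the 21897 protein-coding features matched. It overlaps 1 annotated gene on the opposite strand, so reads in the stretch they share cannot be told apart without the strand.

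All 121 genes of the lists fixed in advance were present in both libraries. Of these, 120 were protein coding, and the exception was Dlx6os1, an antisense RNA gene whose symbol stood on 2 rows. The same identifier version was found in GENCODE M21 for 114 of them. Another annotated gene overlapped 30 of the 121 on the same strand and 48 on the opposite strand.

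Every gene chosen for the lists on inhibitory transmission had a row. The GABA-A receptor is the main fast inhibitory receptor, and the 12 subunit genes chosen for its list included Gabra2, Gabra3 and Gabra4. These 12 had a median span of 120 kb with a median of 95.7% intron. The 6 genes of GABA synthesis and release included Gad1 and Gad2, the GABA-synthesizing enzymes, and Slc32a1. Their median span was 60.3 kb. The 8 inhibitory synapse genes included Gphn, the scaffold protein gephyrin, Nlgn2, an adhesion protein, and Nrxn2, with a median span of 137 kb. Gphn spans 458 kb and Nlgn2 14.7 kb. The 8 potassium and sodium channel genes included Kcnc1, Kcnc2, Kcna1 and Kcna2, with a median span of 173 kb. Introns make up 96.4% of Kcnc2 but 14.1% of Kcna2.

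Activity-regulated genes were the shortest of the 7 gene lists by median span. The 8 members included Fos, Fosb, Junb and Arc and had a median span of 5.56 kb with a median of 30.6% intron, the lowest median among the 7 lists. Junb had another identifier version in GENCODE M21. The 10 genes associated with autism and developmental delay included Shank3, Chd8 and Scn2a and had a median span of 97.1 kb. Shank3 and Scn2a had other identifier versions in GENCODE M21.

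Markers of every cell class listed had rows in both libraries. For inhibitory neurons, 8 general markers (among them Gad1, Gad2 and Slc32a1) were present, with 5 each for the Pvalb class (Pvalb, Tac1, Btbd11 and Kcnc2 among them), the Sst class (Sst, Grin3a, Elfn1 and Chodl), the Vip class (Vip, Calb2, Crh and Cck) and the Lamp5 class (Lamp5, Ndnf, Reln and Id2). The 10 excitatory markers included Slc17a7 and Slc17a6, vesicular glutamate transporters, and Neurod6. Glial lists were complete as well, with 6 astrocyte genes (Aqp4, Slc1a2, Slc1a3 and Gfap among them), 5 oligodendrocyte genes (Mbp, Mog and Mobp), 5 oligodendrocyte precursor genes (Pdgfra, Cspg4, Vcan and Olig1) and 5 microglial genes (Cx3cr1, Csf1r, P2ry12 and C1qa). The 6 vascular markers included Cldn5, Flt1, Pecam1 and Pdgfrb. The 5 markers of the neighbouring striatum included Drd1, Drd2, Ppp1r1b and Adora2a. Presence of a row says that a gene could be counted and says nothing of its expression. The main interneuron peptide genes are short, Sst spanning 1.39 kb and Vip 8.40 kb, while Reln spans 460 kb.

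The control library listed 1951463 barcodes and the cHET library 1817352, with no line repeated and every barcode ending in the suffix 1. Lists of this size include barcodes that hold no nucleus, so they do not give numbers of nuclei. The lists also do not show which barcodes came from a bead in a droplet. Without replicate libraries, the difference between the list sizes has no error against which to be set. In both libraries the first 7 bases took 960 variants and the last 9 bases took 7078, which gives 6794880 possible pairings. The control library listed 28.7% of these pairings and the cHET library 26.7%.

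The libraries had 839099 barcodes in common, and 2929716 were listed in at least 1 of them. The common barcodes made up 43.0% of the control list (95% interval 42.9 to 43.1%) and 46.2% of the cHET list (95% interval 46.1 to 46.2%). Both shares have the same numerator, so they differ only through the list sizes. The intervals treat barcodes as independent, although barcodes are built from a limited set of parts. Independent draws of equally likely pairings would share 521936 barcodes (SD 522), so the observed overlap was 1.61 times that value.

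**Figure D2:**
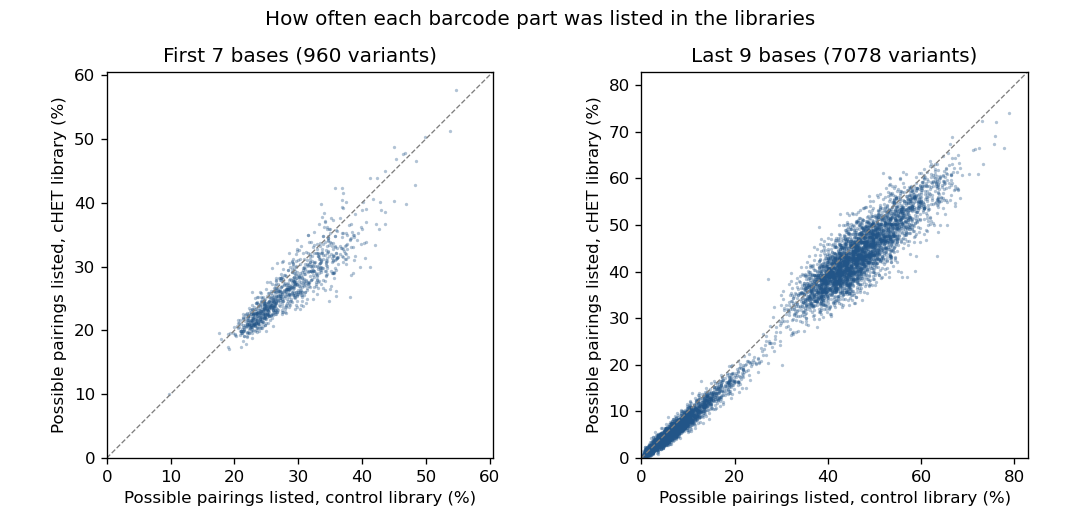
Share of possible pairings listed (%) for each variant of the first 7 bases (left, 960 points) and of the last 9 bases (right, 7078 points), in the control library (x axis) and the cHET library (y axis), with a dashed line of equality. Variants of the last 9 bases ranged from 0.208% to 79.0% in the control library and from 0.104% to 74.1% in the cHET library, in a lower and an upper group that lie along the line.

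The last 9 bases fell into pairs. The final 7 bases took 3539 variants, each of which occurred with exactly 2 versions of positions 8 and 9, counted from the 5' end, and in 3539 of 3539 pairs those versions were base complements. Within each pair, the member listed more often in the control library was also the one listed more often in the cHET library in 3462 pairs (97.8%, against 50% for unrelated lists). In the cHET library, which played no part in that choice, the members listed more often in the control library were seen in a median of 43.3% of their pairings and their partners in 5.63%. The ranges overlapped, so not every pair had a rare member. In that library the 95th percentile was 41.25% for the partners, and the 5th percentile was 33.6% for the members listed more often. The members listed more often made up 81.8% of the control list and 82.3% of the cHET list.

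Base composition was close between the lists. The share of G and C was 49.4% in the control library and 49.5% in the cHET library (95% intervals 49.39 to 49.42% and 49.45 to 49.48%, counting error over bases). These intervals treat bases as independent, although the barcodes are built from a limited set of parts. They therefore do not show whether the libraries differ. By position, the farthest apart was C at the second base, at 24.8% and 25.1%, a difference of 0.279 percentage points. Both lists departed from equal use of the 4 bases, with C at the sixth base at 29.7% in the control library and 29.9% in the cHET library.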

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

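Leaving out the barcode suffix gave the same numbers of barcodes, counting features by symbol gave 55294 in place of 55404, and matching symbols without regard to case found the same number of list genes (121). The pool estimated by capture and recapture was 4220573 from odd-numbered lines and 4226552 from all lines, but thinning both lists leaves this estimate in place by construction, and it assumes equally likely pairings, which unequal rates bias low. Matching only the first 8 bases left 3840 shared items in place of 839099, because the lists hold no more than that number of 8-base starts. Among barcodes in 1 list only, the share of G and C was 49.55% in place of 49.41% in the control library. In the cHET library it was 49.67% in place of 49.46%. This sum hides opposite shifts of C and G. At every position, shared barcodes held more C and less G than barcodes in 1 list only, for both libraries. At the second base, C made up 26.39% of shared barcodes, against 23.56% (only control) and 23.91% (only cHET). At that base G made up 19.42%, against 23.47% and 23.61%. The cause was not tested. The alternatives planned for sums of counts by cell class (another minimum of genes per nucleus, another scaling and another minimum of counts per gene) were not run, since no read counts were analysed. Leaving out a replicate was not possible with 1 library per group, and the depth per barcode is unknown.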

Other observations

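The overlap of the barcode lists was 1.61 times that of independent, equally likely draws, and the explanations below were tested after that overlap had been seen. The test of the remainder was chosen after its result had been seen. Unequal use of the barcode parts was the first explanation. In the control library, variants of the last 9 bases were listed in a median of 37.1% of their possible pairings, but in 3.23% at the 10th percentile and 53.6% at the 90th. Given each part's own frequency in each library, 823900 shared barcodes were predicted, and the ratio of the observed overlap to this prediction was 1.018, within the tolerance of 0.05 around equality set before the ratio was computed. The prediction contained 95.2% of the excess over equal draws, which is consistent with a common pool of barcodes of unequal frequency.

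Reads exchanged between the libraries were the second explanation. The same ratio of 1.018 argues against exchange of barcodes at random as the cause of the whole excess. In simulation, copying 20% of the control list at random into the other list gave ratios of at least 1.145. Those lists were drawn from the fitted rates, and exchange that favours some barcodes was not simulated. A remainder of 15199 shared barcodes stayed above the prediction, and the observed 839099 lay above the highest of 20 simulated overlaps, 825422. Whether this remainder may come from exchanged reads or from barcode frequencies that the parts do not describe cannot be told apart, because the reads per barcode were not analysed. The same model left a like excess, with ratios of 1.020 and 1.023, for partner barcodes that differ at positions 8 and 9 and were listed in different libraries, which cannot be the same tag. No biological explanation was tested.

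The pairs of last parts listed at different rates were also noticed in the data. A candidate explanation is that partner tags sit on the same bead, on oligos of different kinds. Joint listing of partners was compared with the rates of the barcode parts. In the control library 189061 partner pairs were listed together (184220 predicted, ratio 1.026, SD 0.0021) and in the cHET library 159813 (155337 predicted, ratio 1.029, SD 0.0024). Both ratios lay above those across libraries, 1.020 (SD 0.0023) and 1.023 (SD 0.0022), but by less than the margin of 0.05 set before they were computed, and both lay under the bound of 0.05 above equality. Simulated lists, added after these ratios were seen, gave 0.997 to 1.001 with no partners placed together and 1.09 to 1.11 when 10% of the less-listed barcodes were placed with a listed partner, so the bound could be reached. The bound set in advance was applied to all pairs together. By it, the values argue only against capture on a listed partner's bead as the general origin of the less-listed barcodes. Pairs with no rare member entered both the comparison and the simulation, and pairs with a rare member were not compared alone. These values do not decide whether partner tags sit on the same bead, because tags may be listed without their bead having entered a droplet. The kit's own barcode design, which could settle the matter, was not among the sources used here. Capture of a small share of the less-listed barcodes on a listed partner's bead was not excluded, and the within-library ratios were the higher ones.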
